A study of Macrobrachium rosenbergii with 20 samples.

How the data were processed

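RNA from the hepatopancreas and the gonads of adult giant freshwater prawns (Macrobrachium rosenbergii, strain label CMr1) was sequenced, per the labels, after preparation with a directional library kit. The table used here holds 1 column for each of the 20 libraries and 1 line for each of 30260 transcripts, with a length in bases. Its values are estimated counts as deposited by the authors, with no normalisation: library totals differ, and 59.8% of the values above 0 are whole to within 1e-06. Bowtie 0.12.2 and DESeq 1.10.1 are named per the submitters' processing notes, which give neither tool a role. The counting program, the reference transcript set and its filters are not given in the sources used here. Each ID names a quality class (HQ or LQ), the word Female or Male, a number written after f, and a length. The files pair no ID with a gene name, and 0 IDs matched the 31758 genes of the reference gene table (assembly ASM4041242v1). Gene lists fixed before the data were examined, which need gene names, were therefore not tested here.

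Samples were grouped by the tissue and sex in the labels, with 5 replicates per group. The labels do not say whether samples of the same number come from the same animal, or whether replicates are separate animals. Each comparison was fitted on its own 2 groups of 5 libraries. The test of whether the tissue difference differed between sexes used all 20 libraries, with sex, tissue and their interaction as terms. The weight gain slope was fitted within sex on the 10 hepatopancreas libraries and on the 10 gonad libraries. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, library sizes from all transcripts) in R 4.3.3. Transcripts with at least 10 counts in at least 5 libraries of the fit were kept. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 change was its size divided by the square root of the F statistic. Fold values beside mean CPM (counts scaled by library total) come from group count sums over TMM-scaled library sizes, with a 95% Poisson interval. Those CPM are TMM-scaled, while CPM in the presence rule and beside the interaction are scaled by library totals alone. Where a group had no counts, a lower bound against 3 counts over the group is given in place of a fold. Intervals and bounds cover counting error only.

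Library totals ran from 8670654 counts in ovary 2 to 18355664 in male hepatopancreas 1. On simulated counts with a seeded set of changed transcripts, built from the means and library sizes of each comparison, 8-fold changes were recovered in 60.6% of cases in each of the 4 comparisons of groups. Changes of 4-fold were recovered in 47.8% (female against male hepatopancreas, 6582 transcripts), 34.3% (ovary against testis, 7045), 35.8% (ovary against female hepatopancreas, 7107) and 22.4% (testis against male hepatopancreas, 7094). Changes of 2-fold were recovered in 1.5%, 3.0%, 1.5% and 4.5%, in the same order. Only 66 or 67 transcripts were changed per size, far fewer than were called between the gonads and between the tissues. An adjusted p is harder to pass with so few changes, so these shares can understate recovery in those comparisons. Slopes of 1.5-fold per unit of weight gain were recovered in 7.5% of cases in hepatopancreas and 20.9% in gonads. Slopes of 2-fold were recovered in 40.3% and 53.7%, and slopes of 3-fold in 80.3% and 84.8%. Weight gain ran from 4.33 to 7.21 in female and 1.61 to 3.69 in male hepatopancreas samples. It ran from 2.14 to 7.52 in ovary and 1.48 to 2.83 in testis samples. The change across the samples of a group is therefore larger than the slope per unit. False calls made up between 0 and 6.5% of the calls.

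Named transcripts followed a rule fixed before the data were examined: with no gene names, at most 2 per direction and comparison, those of largest change among called transcripts whose groups did not overlap. For the interaction, the 2 called transcripts of largest change per direction were named without the overlap condition. A transcript was taken as present in a group at 1 CPM or more in at least 4 of its 5 libraries. That rule was chosen after the data were seen. Weight gain labels were compared by a two-sided exact permutation test of the difference of means. Principal components were computed from log2 CPM with a prior count of 2. Alternatives fixed beforehand were DESeq2 1.42.0, its size factors, no filter, a filter of 50 counts, all 4 groups in 1 fit, the replicate number as a block, weight gain as a covariate, and leaving out each library. Library totals without TMM, a filter of 10 counts in 4 libraries, leaving out 3 atypical libraries, and presence minimums of 0.5 and 5 CPM were chosen after seeing the data.

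The replicate number was checked as a mark of pairing through the correlation, across transcripts, of deviations from the group means. Male hepatopancreas and testis libraries of the same number correlated at 0.15 to 0.27 in 5 of 5 pairs, each above the correlation with every other number. The numbers were taken to pair these male samples, a pairing that comes from the data. The sample descriptions give both samples of a pair the same sex and number but name no animal. The main fits leave this pairing out, and the replicate block is given as an alternative. The weight gain labels go against these being samples of the same animals: they differed in 5 of 5 male pairs, by 0.01, 0.86, 1.0, 1.35 and 0.03 in males 1 to 5. No library column was a copy of another: the smallest chi-square per degree of freedom among 40 pairs of replicates was 103.9. Microbiome data are not analysed here.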

Results

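Transcript abundance was measured in the hepatopancreas, the digestive gland of crustaceans, and in the gonads of adult female and male giant freshwater prawns. The 20 libraries formed 4 groups of 5: female hepatopancreas, male hepatopancreas, ovary and testis. Library totals averaged 12912657 ± 2682113 counts in female hepatopancreas, 15712552 ± 1786017 in male hepatopancreas, 10711546 ± 2112182 in ovary and 14928426 ± 1538592 in testis (SD, n = 5). Of 30260 transcripts, 10473 had counts in at least 1 library and 5244 in all 20. The other 19787 (65.4%) had no count in any library. Transcripts with the word Male in their ID made up most of these, with 17167 of 17520 (98%) at 0, against 2620 of 12740 (20.6%) of those with the word Female. Male IDs took 16.74% ± 0.85 of the counts in ovary, 5.87% ± 2.85 in testis, 8.06% ± 2.84 in female hepatopancreas and 6.26% ± 1.40 in male hepatopancreas (SD, n = 5).

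Transcripts present in testis only held more counts than those present in all 4 groups in testes 1 to 4, but not in testis 5 (27.5% against 55.4%). By the presence rule, 516 transcripts were present in testis only, and they took 53.32% ± 16.18 of testis counts (SD, n = 5), from 27.5% in testis 5 to 71.2% in testis 1. Another 675 transcripts were present in ovary only and took 26.61% ± 3.63 of ovary counts. The 589 transcripts present in both hepatopancreas groups but in neither gonad took 43.13% ± 6.99 of counts in female hepatopancreas and 53.90% ± 5.35 in male hepatopancreas. A set of 440 transcripts was shared by the gonads alone and took 1.96% ± 0.18 of ovary and 1.87% ± 0.66 of testis counts. The 4341 transcripts present in all 4 groups took 67.95% ± 2.76 of ovary counts but 31.35% ± 5.08 of male hepatopancreas counts. Of the 4 groups, 64 transcripts were present in female hepatopancreas only and 83 in male hepatopancreas only. Transcripts of 1 sex's hepatopancreas that were also present in a gonad are not in these sets. The male set took 3.87% ± 2.31 of male hepatopancreas counts, with 3.29% to 5.40% in males 1 to 4 and 0.057% in male 5. With a minimum of 5 CPM, 2333 transcripts were present in all 4 groups and 1391 in ovary only.

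**Figure D1:**
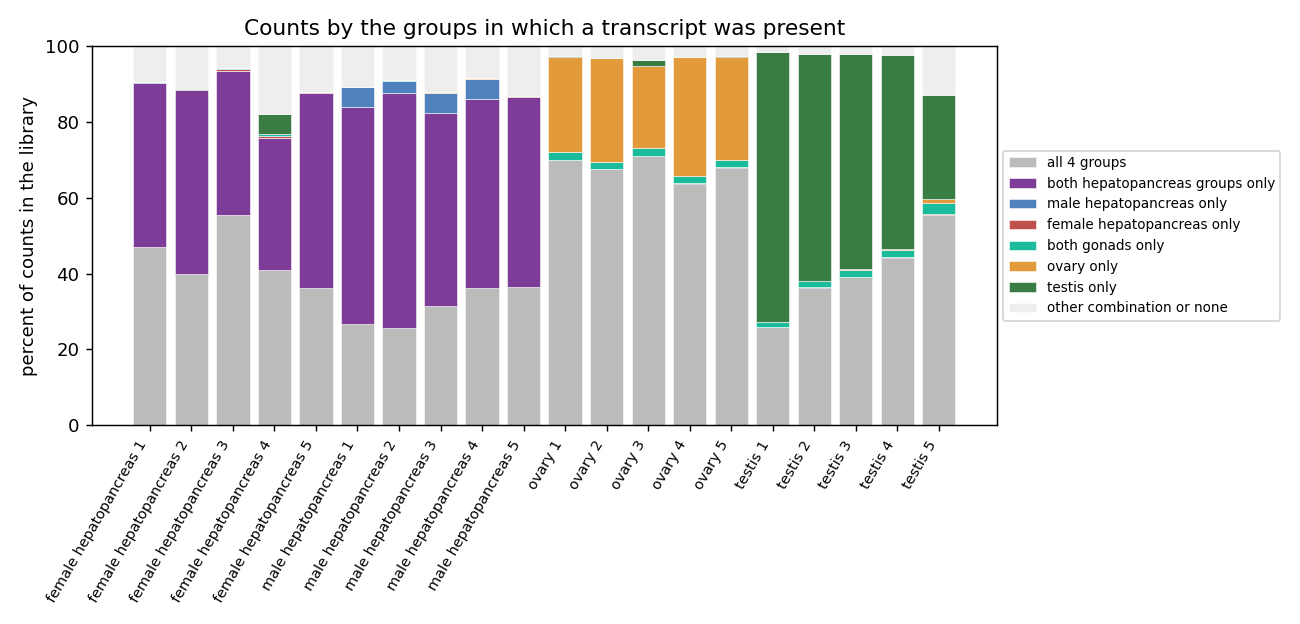
Percent of each library's counts (vertical axis) on transcripts grouped by where they were present, 1 stacked bar per library. Testis-only transcripts take 27.5% to 71.2% of testis counts, and the male hepatopancreas set is at 0.057% in male hepatopancreas 5.

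Gonads and hepatopancreas separated along the first principal component of log2 CPM, which held 55.8% of the variance, and ovary and testis along the second, with 20%. Female hepatopancreas 4 and testis 5 stood apart on the third, which held 4.3%, at scores of 111.78 and 104.48. Male hepatopancreas 5 lay at 18.39 on that component, among female hepatopancreas libraries 1, 2, 3 and 5 (5.17 to 28.53), while the other male hepatopancreas libraries lay between -48.26 and -32.74.

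**Figure D2:**
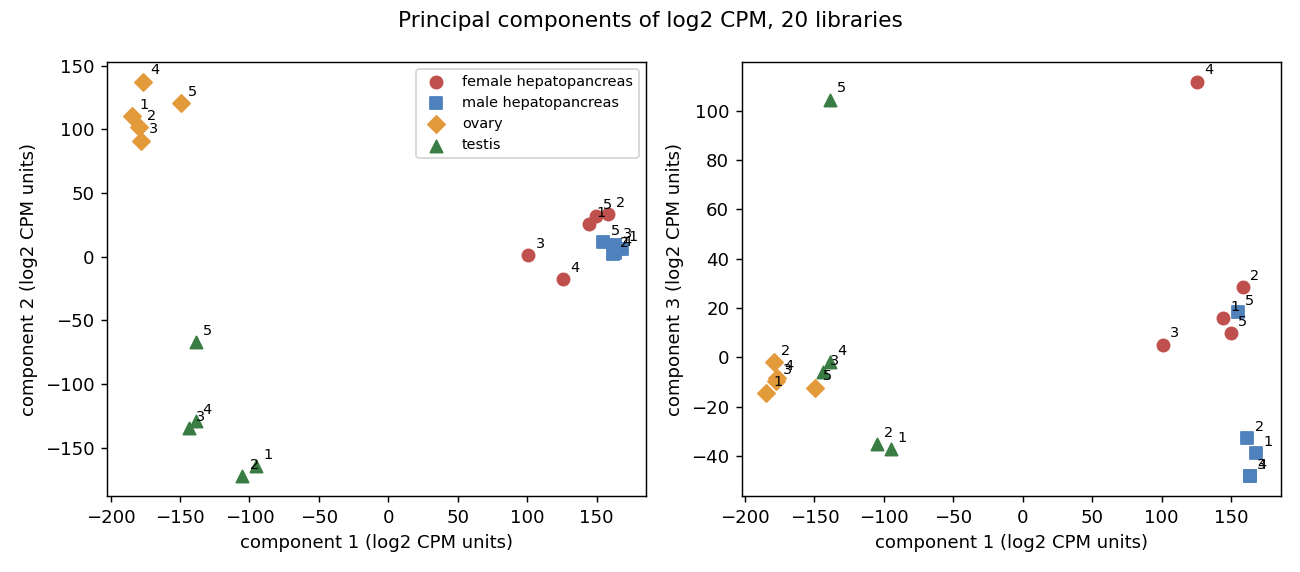
Principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM for 20 libraries, in log2 CPM units, with 1 point per library and its replicate number. Component 3 sets female hepatopancreas 4 (111.78) and testis 5 (104.48) apart from the other libraries.

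Between female and male hepatopancreas, the question was how the digestive gland differs between the sexes. Transcripts differed in both directions. Transcript transcript_HQ_Female_transcript1755/f3p0/2534 averaged 68100 ± 42760 CPM in males and 173.1 ± 155.4 CPM in females (SD, n = 5 each), 405-fold higher in males (95% interval 398 to 412). Transcript transcript_HQ_Female_transcript1499/f11p0/2627 averaged 3746 ± 4805 CPM in males and 17.73 ± 10.28 CPM in females, a 241-fold difference (227 to 255). The intervals beside folds in this comparison cover counting error alone and leave out the spread between libraries. Male 3 alone held 12110 CPM of the latter, and without it the log2 change (female minus male) was -6.55 in place of -7.72. Both were lowest among males in male 5, at 4318 and 27.3 CPM. Higher in females were transcript_HQ_Female_transcript17795/f3p0/1078, at 157.7 ± 112.1 CPM against no count in any male library (at least 2980-fold higher), and transcript_HQ_Female_transcript1570/f3p0/2608, at 62.55 ± 99.71 against 0.92 ± 0.31 CPM (55.7-fold, 43.5 to 72.5). Female 3 held 0.59 CPM of the former, and female 1 held 240.6 CPM of the latter against 12.09 to 26.58 CPM in the other females, with a log2 change of 4.33 without female 1 in place of 6.07. Of 6582 transcripts tested, edgeR called 289, with 144 higher in females and 145 higher in males, and 209 differed at least 2-fold. The called transcripts had a median length of 998 bases where higher in females and 1916 where higher in males, against 1634 for those tested. The 2 groups did not overlap for 625 transcripts (9.5%), where chance gives 0.79%. The log2 changes (female minus male) of the named transcripts with counts in both sexes were -8.62 ± 1.99, -7.72 ± 1.70 and 6.07 ± 1.04 (SE), and edgeR adjusted p of all 4 ran from 0.036 to 0.0427.

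The number of calls in this comparison changed when single libraries were left out. All 289 calls had an edgeR adjusted p between 0.036 and 0.05, so small shifts can move many of them past 0.05 at once. It was 740 without male hepatopancreas 5 and 616 without female hepatopancreas 3, and 286 and 276 of the 289 were among them. It fell to 2 without female hepatopancreas 1, and to 0 in edgeR without any 1 of female hepatopancreas 2, 4 or 5 or male hepatopancreas 1, 2, 3 or 4. Those fits with 0 calls held 1352 to 1649 transcripts at an unadjusted p under 0.05, against 1750 with all libraries. DESeq2 called 1223 on all 10 libraries, 287 of the 289 among them.

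Between ovary and testis, the question was how the gonads differ. The largest differences were transcripts abundant in 1 gonad and without a count in the other. Transcript transcript_HQ_Female_transcript14064/f5p0/1257 averaged 15790 ± 3687 CPM in ovary (SD, n = 5) and had no count in testis, at least 254000-fold higher. Transcript transcript_HQ_Male_transcript13430/f2p0/1591 averaged 7171 ± 1972 CPM in ovary and had no count in testis, at least 118000-fold higher. In testis, transcript_HQ_Female_transcript22039/f2p0/704 averaged 42290 ± 38030 CPM and transcript_LQ_Female_transcript21054/f2p0/819 averaged 15400 ± 17450 CPM, both without a count in ovary (at least 886000-fold and 307000-fold lower there). Testis 5 held only 23.87 and 2.67 CPM of these, and testis 4 held 237.3 CPM of the latter. Testis 1 held the most, 104300 and 42570 CPM, and without it the testis means were 26790 and 8602 CPM. EdgeR called 4009 of 7045 transcripts, 1904 higher in ovary and 2105 higher in testis, and 3605 differed at least 2-fold. Differences of at least 32-fold were found for 174 ovary-higher and 421 testis-higher transcripts. The groups did not overlap for 3094 transcripts (43.9%), where chance gives 0.79%. Adjusted p in edgeR was 1.72e-05 and 1.35e-05 for the ovary transcripts named and 0.00135 and 0.00387 for the testis ones.

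The balance of calls between ovary and testis rested on the scaling. TMM gave 47.5% of calls as higher in ovary, and library totals without TMM gave 76.9% of 4232 calls, with the median log2 change of all transcripts 1.27 higher. On totals alone the corresponding shifts were 1.66 for ovary against female hepatopancreas, 0.86 for testis against male hepatopancreas, 0.44 for female against male hepatopancreas and 0.75 for the interaction. The changes named here are larger than these shifts.

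In females, ovary was compared with hepatopancreas to find what sets the gonad apart from the digestive gland. Transcript transcript_HQ_Male_transcript24463/f3p0/1117 averaged 2711 ± 427.8 CPM in ovary and transcript_HQ_Female_transcript11875/f6p0/1412 averaged 2298 ± 442.3 CPM (SD, n = 5), both without a count in female hepatopancreas (at least 32600-fold and 27600-fold higher in ovary). Transcript transcript_HQ_Female_transcript3013/f41p0/2160 averaged 993.9 ± 720.9 CPM in female hepatopancreas and transcript_HQ_Female_transcript15076/f23p0/1181 averaged 738.8 ± 585.7 CPM, both without a count in ovary (at least 26800-fold and 19900-fold lower there). EdgeR called 4732 of 7107 transcripts, 2385 higher in ovary and 2347 higher in hepatopancreas, and 4266 differed at least 2-fold. At least 32-fold differences numbered 345 toward ovary and 821 toward hepatopancreas. Adjusted p in edgeR was 4.56e-06, 4.53e-06, 6.64e-05 and 0.00012 for the 4 transcripts in the order named. The groups did not overlap for 3891 transcripts (54.7%, against 0.79% by chance). Without TMM, 78.1% of 5114 calls were higher in ovary, against 50.4% with it.

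In males, testis was compared with hepatopancreas for the same purpose. Transcript transcript_LQ_Female_transcript21746/f2p0/788 averaged 38090 ± 31570 CPM in testis and transcript_HQ_Female_transcript2895/f2p0/2230 averaged 22210 ± 22490 CPM (SD, n = 5), both without a count in male hepatopancreas (at least 572000-fold and 319000-fold higher in testis). Testis 5 held 8.58 and 1.32 CPM of these, against 18040 to 80640 and 9360 to 57510 CPM in the other testis libraries. Without testis 1, which held the most of both, the testis means were 27450 and 13380 CPM. Transcript transcript_HQ_Female_transcript1564/f8p0/2607 averaged 1310 ± 729.4 CPM in male hepatopancreas and transcript_HQ_Female_transcript6151/f483p0/1758 averaged 601.9 ± 1124 CPM, both without a count in testis (at least 43600-fold and 25800-fold lower there). Male hepatopancreas 5 held 2607 CPM of the latter, against 33.24 to 225.1 CPM in the other males, whose mean was 100.6 CPM. EdgeR called 3411 of 7094 transcripts, 1782 higher in testis and 1629 higher in hepatopancreas, and 3020 differed at least 2-fold. That fit left the pairing by number out. With the replicate block, edgeR called 3237, and 3013 of the 3411 were among them. At least 32-fold differences numbered 245 toward testis and 721 toward hepatopancreas. Adjusted p in edgeR was 0.00274, 0.00374, 2.83e-05 and 0.00271 for the 4 transcripts in the order named. The groups did not overlap for 2554 transcripts (36.0%, against 0.79% by chance). Without TMM, 74.4% of 4257 calls were higher in testis, against 52.2% with it.

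The difference between gonad and hepatopancreas was itself compared between the sexes. The same test sets the sex difference of the gonads against that of the hepatopancreas, where 4009 and 289 transcripts were called. Differences between ovary and testis therefore enter it. Transcript transcript_HQ_Female_transcript12136/f5p0/1399 was an ovary transcript, at 8009 ± 1214 CPM in ovary and at most 0.20 CPM in any library of the other groups (SD, n = 5). Of the male libraries only male hepatopancreas 3 (0.195 CPM) and testis 5 (0.058 CPM) held any, so its tissue difference in males rested on these. Transcript transcript_HQ_Male_transcript27571/f2p0/948 averaged 430.7 ± 78.34 CPM in ovary and 5.08 ± 4.73 CPM in male hepatopancreas, with no count in testis or female hepatopancreas. In the opposite direction, transcript_HQ_Female_transcript8354/f20p0/1558 and transcript_HQ_Male_transcript21106/f4p0/1257 rested on single libraries. They reached 497.2 and 340.7 CPM in female hepatopancreas 4 and 397.5 and 457.6 CPM in testis 5, and at most 5.42 CPM elsewhere. The interaction was called by edgeR for 3013 of 8043 transcripts, in a fit without pairing. With the replicate block, 2709 were called, and 2399 of the 3013 were among them. Of the 3013, the gonad minus hepatopancreas difference was higher in females for 1308 and higher in males for 1705, whichever tissue was higher. This balance turned without testis 5, to 1718 toward females and 1552 toward males, and without the 3 atypical libraries (female hepatopancreas 4, male hepatopancreas 5 and testis 5), to 1546 and 1284. Adjusted p in edgeR was 4.01e-06, 3.82e-05, 0.0034 and 0.00512 for the 4 transcripts in the order named. Without TMM, 64.4% of 2693 calls were toward females, against 43.4% with it.

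Sex differences in the hepatopancreas and in the gonads showed no correlation beyond its error across transcripts in the fits with all libraries and no further term. Tissue differences in females and males were positively correlated. For the sex difference, Pearson's r was -0.003 and Spearman's rho 0.10 over 5833 transcripts (jackknife SE of r 0.23 over libraries). Pearson's r was 0.34 with weight gain as covariate, 0.20 with the replicate block and 0.21 without the 3 atypical libraries, with no SE computed for these. Of the calls shared by both comparisons, 57 were higher in females, against 39.3 for independent lists, and 53 were higher in males, against 34.8. Opposite calls numbered 49 for transcripts higher in female hepatopancreas and in testis, against 42.6, and 17 for those higher in male hepatopancreas and in ovary, against 32.1. For the tissue difference, r was 0.78 and rho 0.53 over 6520 transcripts (jackknife SE 0.18). Gonad-higher in both sexes were 691 transcripts, against 468.8 for independent lists, and hepatopancreas-higher 1204, against 546.7. Opposite calls were found for 84 transcripts gonad-higher in females and hepatopancreas-higher in males, against 474.3, and for 284 the other way, against 540.3. These correlations are across transcripts, which are not independent replicates, and the 2 comparisons in each shared no library. The sex comparisons are still not independent of each other, because same-numbered male hepatopancreas and testis samples deviated together in 5 of 5 pairs (and female ones in 4 of 5). The independent-list values and the jackknife SE leave this out, and shared sex calls were not tested against it.

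Females carried higher weight gain labels than males. The hepatopancreas samples of females had a weight gain of 5.96 ± 1.45 against 2.59 ± 0.80 in males (SD, n = 5 each, unit not stated in the labels), a difference of 3.37 (two-sided exact permutation p 0.00794, the smallest that 5 against 5 samples allow; Benjamini-Hochberg adjusted 0.0159 over 2 tests). Ovary samples had 4.86 ± 2.0 against 2.34 ± 0.57 in testis samples, a difference of 2.52 (exact permutation p 0.0317, adjusted 0.0317). Without ovary 2, 3, 4 or 5 the gonad difference was 2.31, 2.75, 2.49 or 1.86, and without testis 1 or 4 it was 2.45 or 2.30, and each of these no longer passed 0.05. Weight gain thus differed along with sex in these samples. The label also differed between the hepatopancreas and gonad samples of the same number in 10 of 10 pairs (by 0.01 to 3.09, median 1.21).

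**Figure D3:**
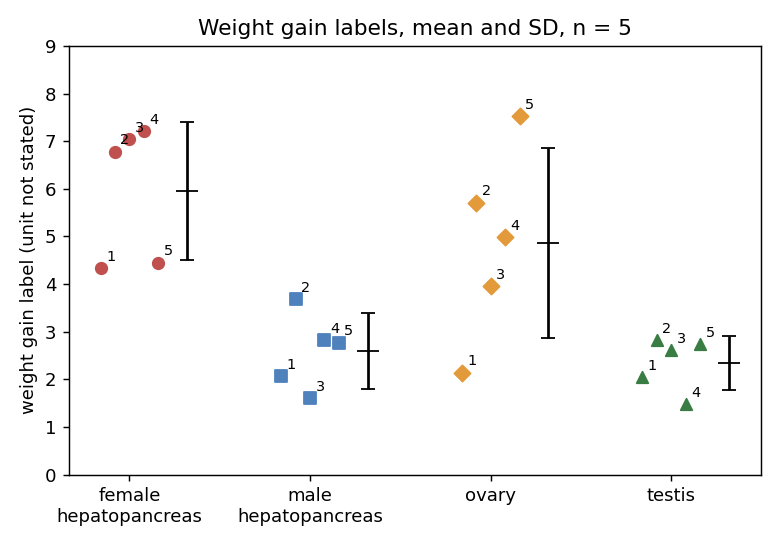
Weight gain label of each sample (vertical axis, unit not stated) by group, with 1 numbered point per sample and the mean and SD beside them (n = 5). Female hepatopancreas samples average 5.96 and male ones 2.59.

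No transcript was called for weight gain within sex in either tissue by edgeR. Simulated slopes of 2-fold per unit were recovered in only 40.3% of cases in hepatopancreas and 53.7% in gonads, so associations can have been missed. In hepatopancreas, 405 of 6582 transcripts (6.2%) had an unadjusted p under 0.05, the smallest adjusted p was 0.751, and DESeq2 called 98. In gonads, 175 of 7045 (2.5%) had an unadjusted p under 0.05, the smallest adjusted p was 0.917, and DESeq2 called 23. With weight gain as a covariate, ovary against testis kept 2584 of its 4009 calls among 2619. Female against male hepatopancreas kept 0 of 289 in edgeR under the same covariate, with 631 transcripts at an unadjusted p under 0.05. Weight gain labels did not overlap between the sexes there (4.33 or more in females, 3.69 or less in males). That fit therefore separated sex from weight gain poorly, and its 0 calls do not show that weight gain accounts for the sex difference. All 289 kept their sign, and their median absolute log2 change was 1.24 without and 1.24 with the covariate, while the median SE went from 0.26 to 0.50. Of the named ones, transcript_HQ_Female_transcript1570/f3p0/2608 went from 6.07 ± 1.04 to 8.41 ± 1.09 and transcript_HQ_Female_transcript1499/f11p0/2627 from -7.72 ± 1.70 to -5.32 ± 3.11 (log2 change, SE).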

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

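All tests of explanations in this part were chosen after the results were seen, and only the interaction test was fixed beforehand. In each group of 5 libraries, a library was singled out where its gap to the nearest other library exceeded 0.71 of the group's range. For independent, normally spread values chance does this in about 1 of 20 groups. Here 17 of 74 sets of 5 values showed it. These sets share libraries and include transcripts chosen for large changes, so the rates cannot be compared. Female hepatopancreas 4 had 5.278% of its counts on testis-only transcripts (0.016% to 0.062% in the other female hepatopancreas libraries), 0.519% on transcripts of the gonads alone and 0.226% on the male hepatopancreas set. Ovary 3 had 1.606% on testis-only transcripts (0.032% to 0.099% in the other ovaries), and ovary 5 had 0.224% on transcripts of both hepatopancreas groups. Male hepatopancreas 4 had 0.042% on testis-only transcripts, and male hepatopancreas 5 had 0.166% on the female hepatopancreas set (0.012% to 0.045% in the other males). Testis 5 had 10.79% on Male IDs (3.45% to 5.40% in the other testes) and 0.187% on the female hepatopancreas set.

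Among named transcripts, transcript_HQ_Female_transcript1499/f11p0/2627 stood at 0.127 CPM in female hepatopancreas 3 (18.16 to 25.36 in the other females) and at 12110 CPM in male hepatopancreas 3. Transcript transcript_HQ_Female_transcript1570/f3p0/2608 stood at 240.6 CPM in female hepatopancreas 1, and transcript_HQ_Female_transcript6151/f483p0/1758 at 2607 CPM in male hepatopancreas 5. Transcripts transcript_HQ_Female_transcript8354/f20p0/1558 and transcript_HQ_Male_transcript21106/f4p0/1257 stood at 497.2 and 340.7 CPM in female hepatopancreas 4 and at 397.5 and 457.6 CPM in testis 5. The gonad against hepatopancreas difference differed between the sexes for 3013 transcripts by the interaction test.

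Nearly all transcripts with a Male ID had no count. If the f number rises with abundance, which the sources used here do not state, rarity of the transcripts runs against the values. Of Male-ID transcripts with an f number of at least 10, 97.3% had no count, against 2.8% of Female-ID ones. Reads taken by Female-ID copies, with the words marking the sex of the animals, would leave testis-only transcripts with Male IDs, but 2.1% of them carried one. Swapped words would put Male IDs on most ovary-only transcripts, and 6.7% carried one. What produced the empty transcripts stays open, since the reference set and its filters are not given in the sources used here.

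Female hepatopancreas 4 and testis 5 shared 255 transcripts over 4-fold above every other library of their tissue, against 29.1 for independent lists. These took 11.58% and 18.57% of the 2 libraries and at most 0.23% of any other, at a median ratio of 0.68. Carry-over from testis 5 would bring all its abundant testis-only transcripts at a like ratio, but of 19 over 1000 CPM in testis 5, 14 lay at a ratio of at most 1.1e-06 and the other 5, all among the shared ones, at 0.38 to 0.71. Carry-over from female hepatopancreas 4 would need ratios near 1.47 in testis 5, but 61 of 61 hepatopancreas-only transcripts over 1000 CPM lay at 0.007 or less. Another tissue dissected along in both samples cannot be told apart from a shared state of these animals by the count of 255, because the IDs carry no gene names.

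Male hepatopancreas 5 lay with the females: on a scale from the female mean (0) to the male mean (1) it stood at 0.26 on 140 male-high transcripts chosen without it, and the other males at 1.00 to 1.11 on their own sets of 17 to 20, chosen in the same way. A swap between the sexes would need a female at the male end, and the highest female stood at 0.36 (sets of 21 to 31). Low depth would lower detection, but 7855 transcripts were detected, with 7645 in the lowest of the other males. Testis 5 in turn held under 1% of the usual level of 42 of 47 testis-only transcripts that exceeded 1000 CPM in testes 1 to 4, while the other testes lacked 0 or 1 of only 4 to 6 that qualified, since testis 5 was then among the libraries required. For the hepatopancreas sample, a wrong label and a state of male 5 cannot be told apart, because the labels name no state, and a wrong label there leaves testis 5 unexplained.

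Other splits of the same libraries were counted for each comparison, 100 in each case with the real one included. Only the real split gave as many calls for female against male hepatopancreas (289 calls, highest other 1) and ovary against testis (4009, highest other 510). The same held for ovary against female hepatopancreas (4732, highest other 0) and testis against male hepatopancreas (3411, highest other 2). For samples that are not paired, chance is thus unlikely, though 100 splits do not exclude it. Between female and male hepatopancreas the real split also parts the weight gain labels (4.33 or more in females, 3.69 or less in males). The count there also fell to 0 without any 1 of several libraries. In testis against male hepatopancreas, the paired comparison, 13 of the splits parted all 5 same-numbered pairs. The highest of them apart from the real one gave 0 calls in edgeR. The real split had 3895 transcripts at an unadjusted p under 0.05 and 3651 DESeq2 calls. With only 13 such splits a share under 0.05 is out of reach, so they cannot exclude chance for paired samples. For the interaction the count decides nothing (3013, 2 splits as large, highest other 3141): shuffling sex also removes the sex difference of the gonads, and the split with 3141 calls was one that kept all 5 ovaries on 1 side. For weight gain it decides nothing either: the real order gave 0 calls in edgeR (405 and 175 transcripts at an unadjusted p under 0.05, DESeq2 98 and 23), so all 100 orders gave as many by construction. The highest others gave 1 call in hepatopancreas and 51 in gonads.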

How the results depend on the processing

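Settings chosen after the data were seen were library totals without TMM, the filter of 10 counts in 4 libraries, leaving out 3 atypical libraries (female hepatopancreas 4, male hepatopancreas 5 and testis 5) and both presence minimums. Of the values that answer a comparison, 22 alternative values moved and 7 were weaker. The other 192 stayed: counts within 1.5-fold, others by threshold or spread, leaving out direction. The correlation of sex differences, near 0, was positive in 17 and negative in 13 of 30 alternatives. The balance of calls turned in every comparison under some alternative: the interaction went from 43.4% toward females to 52.5% without testis 5, 54.6% without the atypical libraries and 64.4% without TMM, testis-higher calls from 52.2% to 43.0% without testis 1 and 46.4% with median-of-ratios factors, and ovary-higher calls from 47.5% to 50.8% without testis 5 (against testis) and from 50.4% to 46.6% with median-of-ratios factors (against hepatopancreas). Of those of named transcripts, 286 stayed and 47 were weaker, in the same direction, nearly all in female against male hepatopancreas. Transcripts without a count in 1 group failed the filter of 5 libraries once a library of the other group was left out, so those fits did not test them.

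Female against male hepatopancreas moved most from its 289 calls. EdgeR gave 0 without a filter, 0 with the replicate block, 0 with weight gain as covariate and 0 on library totals without TMM, with 2058, 1361, 631 and 1841 transcripts at an unadjusted p under 0.05. The stricter filter gave 456, DESeq2 1223 and leaving out the atypical libraries 437. Leaving out 1 library gave 0 to 740. Causes were not tested. No filter tests more transcripts (9738), the block costs degrees of freedom and the covariate raised the median SE.

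Ovary against testis had 2619 calls with weight gain as covariate, and 3478 to 4083 leaving out 1 library. The ranges leaving out 1 library were 4064 to 4429 for ovary against female hepatopancreas, 2566 to 3206 for testis against male hepatopancreas and 2617 to 3270 for the interaction. Weight gain slopes gave 98 (hepatopancreas) and 23 (gonads) calls with DESeq2, and 0 leaving out each library with edgeR. The cause was not tested.

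The correlation of sex differences was 0.34 with weight gain as covariate (-0.04 to 0.22 leaving out 1 library, highest without female hepatopancreas 4), and that of tissue differences was 0.51 without a filter (0.68 to 0.79). The gonad weight gain difference was 2.37 by medians and 1.86 to 3.20 leaving out 1 sample, and no longer passed 0.05 by medians or without ovary 2, 3, 4 or 5 or testis 1 or 4. The hepatopancreas one was 3.06 to 3.78 leaving out 1 sample and passed throughout. At 5 CPM, 2333 transcripts were present in all groups and 1391 in ovary only.

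With the replicate block, the paired male comparison gave 3237 calls and the interaction 2709, and no count other than that of female against male hepatopancreas moved by over 1.5 times. The other numbers were not taken as pairs, since not every correlation exceeded 0.1: same-numbered female hepatopancreas and ovary correlated at -0.08 to 0.38 (4 of 5 over 0.1, all but female 4, and 3 of 5 best with their own number; block 4617), female and male hepatopancreas at -0.05 to 0.08 and ovary and testis at -0.09 to 0.08 (block 3592). Not run were the pseudocount of 0.1 and sample weights, which are for normalised values, and the gene list tests, which need gene names. Changes of 2-fold were recovered in 1.5% to 4.5% of simulated cases, with few transcripts changed, which was not split by depth or abundance.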

Other observations

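The test in this part was chosen after the result was seen. Ovary-only transcripts carried Male IDs more often than testis-only ones, in 45 of 675 (6.7%) against 11 of 516 (2.1%; two-sided Fisher's exact test p 0.000257). That test takes each transcript as independent, which transcripts need not be, and its p does not measure spread between samples. In female hepatopancreas 3, 196 transcripts lay over 4-fold above every other hepatopancreas library and took 15.26% of its counts. In female hepatopancreas 4 the same measure gave 620 transcripts and 18.08%. Male hepatopancreas 4 had 16 transcripts with 8.08%, and the remaining hepatopancreas libraries had fewer, with at most 1.07%. TMM factors were 2.37 to 2.63 in ovary, 0.60 to 1.57 in testis and 0.46 to 0.99 in hepatopancreas.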
